A study of Arabidopsis thaliana with 6 samples.

How the data were processed

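RNA sequencing compared whole seedlings (root, hypocotyl and cotyledons) of Arabidopsis thaliana wild-type Columbia with seedlings of athb1-1, a mutant of the transcription factor gene ATHB1. The labels give 3 libraries per genotype and call them biological triplicates. Per the labels' protocols, seeds were stratified for 3 days, seedlings grew in 8 h of light and 16 h of darkness at 22 to 24 degrees C, and harvest came 1 h before the night ended. The labels give the age as 4 days and also state 72 h after stratification. Total RNA was extracted with a column kit, per the labels' protocols.

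The deposited gene files hold raw read counts per gene and the deposited exon files hold raw read counts per exon bin, both as whole numbers with a different total in each library. Reads were aligned to the TAIR10 genome build with TopHat2 2.0.8 and Bowtie2 2.1.0, per the submitters' processing notes. The counting program, its strand setting and the annotation release are not given in the sources used here. In the exon files a read that spans several bins adds to each. Some overlapping genes are merged into 1 locus there, while others, such as MRD1 and HEI10, stay separate. The authors also deposited a table that compares the genotypes, with log2 fold changes and mean log2 CPM per gene. Its log2 fold changes are positive for genes higher in wild-type, and their sign was turned here. The same deposited table gives p-values and adjusted p-values, whose tool and settings the file headers do not name. It further holds 6 columns of per-library signal that the authors scaled to a similar total, and these were not used.

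Gene names came from the TAIR10.1 annotation, which held 32835 of the 33602 gene identifiers in the count files. Gene and exon positions are also those of TAIR10.1, counted from 1. They were not taken from the authors' files, which give no positions.

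Changed genes were tested on the gene counts of all 6 libraries with edgeR 4.0.16 in R 4.3.3. The fit used TMM normalization, the default filterByExpr filter and the robust quasi-likelihood F-test with genotype as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are athb1-1 over wild-type, and a standard error (SE) is the log2 fold change divided by the square root of its F statistic. CPM values were scaled with the TMM factors, and spreads are SD over 3 libraries. Ratios of genes with few counts carry 95% intervals that cover counting error only.

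The test of ATHB1 was planned on its gene counts, which were 0 in every library. Exon bin counts were therefore summed per locus and tested with the same edgeR settings, a choice made after the counts were seen. Exon usage was tested on the exon bins with edgeR's diffSpliceDGE, which asks whether a bin's share of its gene's reads differs between genotypes. Its Simes p per gene was adjusted by Benjamini-Hochberg.

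Before the data were examined, 27 gene lists were fixed by name and 2 more by genome, the plastid-encoded and the mitochondrion-encoded genes. The lists fixed by name covered other HD-Zip I factors, phytochrome and PIF signalling, PIF-induced growth, the circadian clock, expansins, xyloglucan endotransglucosylase/hydrolases (XTH), cellulose synthesis, arabinogalactan and fasciclin-like proteins, root hairs, root markers and photosynthesis. They also covered seed storage, Aux/IAA and GH3 genes, SAUR genes, brassinosteroid, gibberellin, ABA and dehydration, jasmonate, salicylate and pathogen defence, glucosinolates and flavonoids. The remaining lists were iron deficiency, carbon starvation, heat shock, touch and cold, cell division and class III peroxidases. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 29 lists. The tests, thresholds, lists and rule for named genes were also fixed before the data were examined.

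The rule named ATHB1 and, among called genes whose mutant libraries all lay on 1 side of the wild-type libraries with a mean of at least 1 CPM, up to 10 in each direction. For a list past the camera threshold it named the 2 members with the smallest p, and for other lists the 1 with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

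The fits were tested on simulated counts drawn from the real libraries' means and sizes. In the simulated comparison of athb1-1 with wild-type, 85 of 100 genes changed by a log2 fold change of 1 and 97 of 98 changed by 2 were recovered, among 18453 genes tested. Of 195 calls, 13 were false. The simulation changed many more genes than the 10 called in the real libraries, which eases the adjusted threshold. Its recovery can therefore exceed that in the real data. In the simulated list test, 20 of 20 lists shifted by 0.5 were recovered and 0 of 20 others were called. Simulated genes were drawn independently, so this cannot show how camera behaves where genes of a list move together. The shift was also larger than the medians of the real lists past camera, which ran from −0.36 to 0.35. In the simulated exon usage test, 93 of 100 genes with a bin changed by 2 were recovered with 3 false calls, among 12598 genes.

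Alternatives fixed beforehand were DESeq2 median-ratio size factors, upper-quartile normalization, no count filter, a filter of 1 CPM in 3 libraries, organelle genes left out, a replicate block, each library left out in turn, the Wald test of DESeq2 1.42.0 and limma-voom. For lists they also included camera with an estimated correlation and fry, and for exon usage the gene-level F-test. Summed exon bins, removal of a transcript length trend from each library by a lowess offset, and that removal without wild-type replicate 2 were chosen after seeing the data.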

Results

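RNA from whole Arabidopsis seedlings was sequenced in 6 libraries, 3 from wild-type Columbia and 3 from athb1-1. Gene counts totalled 11036314 to 11974342 per wild-type library and 12841376 to 13153615 per athb1-1 library. Exon bins, in which a read can count more than once, totalled 12879069 to 15410157. Between 22362 and 22644 genes had at least 1 count. Libraries of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom of 4.48 to 13.4. Wild-type replicate 2 stood apart from the other libraries. Its counts of seed storage protein and oleosin genes summed to 55.8 CPM, against 2.03 to 9.01 CPM in the other 5 libraries. Its plastid-encoded genes took 0.321% of counts, against 0.163 to 0.280% elsewhere, and its short transcripts were over-represented, with a median log2 deviation from the mean library of 0.11 in the shortest 10% of transcripts and −0.21 in the longest 10%. In the shortest 10%, athb1-1 replicates 1 and 2 deviated the same way (0.04 and 0.07). Wild-type replicates 1 and 3 (−0.09 and −0.08) and athb1-1 replicate 3 (−0.03) deviated the other way.

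The comparison of the genotypes asks which transcripts differ when ATHB1, a homeodomain-leucine zipper class I transcription factor, is mutated. ATHB1 (AT3G01470; TAIR10.1 chromosome 3, 182396 to 184403, minus strand) was reported first because it checks the labels. Its transcript was 47.2-fold lower in athb1-1, at 8.57 ± 0.504 CPM against 405 ± 40.5 CPM in wild-type (SD, n = 3, summed exon bins), so 2.12% of the wild-type level remained. All 3 libraries labelled athb1-1 lay below all 3 labelled wild-type. Exon 1 (183947 to 184403) kept 4.28% of its wild-type level, with 80 to 99 counts per athb1-1 library against 1604 to 1921. Exons 2, 3 and 4 kept 0.901%, 1.03% and 1.08%. The log2 fold change was −5.56 (SE 0.12), with an adjusted p of 7.36e-11 over 18764 loci (edgeR quasi-likelihood test, Benjamini-Hochberg). The bins belong to a locus that merges ATHB1 with the overlapping model AT3G01472, and the gene count of ATHB1 was 0 in all 6 libraries, so reads of the 2 models cannot be separated. Of 237 such merged loci, 46 had 0 gene counts throughout, 35 of these had at least 10 bin counts in every library, and 1, that of ATHB1, passed the threshold.

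**Figure D1:**
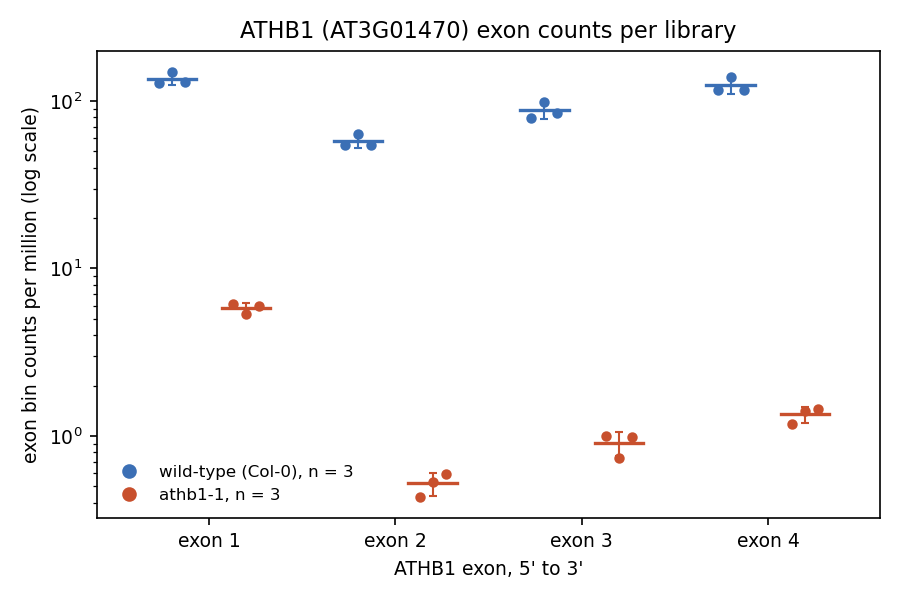
Exon bin CPM (log scale) of the 4 exons of ATHB1, ordered from 5′ to 3′, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3 wild-type in blue, n = 3 athb1-1 in red). Every athb1-1 point lies below every wild-type point, and exon 1 keeps 4.28% of its wild-type level.

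Among the other transcripts, 10 changed with all 6 libraries. Of 18626 genes tested, 4 rose and 6 fell in athb1-1. The uncharacterised gene AT3G01345 (chromosome 3, 129138 to 130749) fell from 192 ± 15.7 CPM to 0.854 ± 0.310 CPM (SD, n = 3). CYP97B3 (AT4G15110; chromosome 4, 8629647 to 8633118), of a cytochrome P450 family that hydroxylates carotenoids, rose from 7.36 ± 1.96 to 35.0 ± 1.80 CPM. FRO4 (AT5G23980; chromosome 5, 8097978 to 8101330), a ferric reduction oxidase of metal uptake, rose from 10.2 ± 0.357 to 19.0 ± 1.07 CPM. The meiotic crossover gene HEI10 (AT1G53490; chromosome 1, 19963267 to 19966952) fell from 4.03 ± 0.527 to 0.730 ± 0.166 CPM. Its neighbour MRD1 (AT1G53480; chromosome 1, 19963047 to 19964712) had 125 counts in wild-type and 1 in athb1-1, a ratio of 145 with a 95% counting interval of 25.6 to 5790.

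In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, AT3G01345 had a log2 fold change of −7.79 (SE 0.18, adjusted p 1.53e-10) and CYP97B3 one of 2.24 (SE 0.16, adjusted p 3.34e-05). By the same test, the pseudogene AT5G35935 (chromosome 5, 14083388 to 14089891) rose by 3.63 (SE 0.20, adjusted p 2.83e-06). AT5G42770 (chromosome 5, 17151988 to 17154618) rose by 2.81 (SE 0.22, edgeR adjusted p 1.09e-04). MRD1 had an edgeR adjusted p of 1.09e-04, HEI10 a log2 fold change of −2.44 (SE 0.26, adjusted p 0.00200) and AT4G16745 (chromosome 4, 9411823 to 9414897) one of −1.28 (SE 0.14, adjusted p 0.00231). AT5G35940 (chromosome 5, 14090574 to 14093007) fell by 1.58 on the log2 scale (SE 0.19, edgeR adjusted p 0.00615). FRO4 rose by 0.90 (SE 0.11, edgeR adjusted p 0.00677), and AT5G40720 (chromosome 5, 16297300 to 16300037) fell by 1.28 (SE 0.19, edgeR adjusted p 0.0304). Positions are those of TAIR10.1. Each of the 10 had all athb1-1 libraries on 1 side of all wild-type libraries. Among all genes tested, 11.3% had groups that did not overlap, where chance gives 10%, and 976 had an unadjusted p under 0.05.

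MRD1 and HEI10 overlap by 1446 bp on opposite strands, and the strand setting of the counting is not given in the sources used here, so their reads cannot be told apart where they overlap. The long non-coding RNA gene AT1G07887 overlaps MRD1 by 1039 bp on the opposite strand and HEI10 by 839 bp on the same strand, and HEI10 also overlaps MUM4 by 9 bp. AT4G16745 overlaps an antisense RNA gene by 329 bp, with the same limit. FRO4 lies beside its paralog FRO5, which was at 10.9 ± 2.78 CPM in wild-type and 16.4 ± 4.23 CPM in athb1-1 (log2 fold change 0.60, SE 0.23, edgeR adjusted p 0.939), and reads of the 2 genes could have been divided between them. FRO5 was chosen after its values were seen.

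The number of changed genes depended on wild-type replicate 2. Without it, 71 genes were higher and 94 lower in athb1-1, 165 in all, among them all 10 of the genes above. All 165 had the same direction with 6 libraries, but these include every library of the smaller fit, so the shared direction is no independent support. Among the fixed lists these were the xyloglucan enzymes XTH15 (0.58) and XTH8 (0.43), the branched-chain amino acid and raffinose enzymes BCAT2 (−0.51) and DIN10 (−0.45), the ferritin FER1 (−0.74), the vegetative storage protein VSP1 (−1.02) and the clock gene LNK2 (AT3G54500, −0.36), as log2 fold changes. XTH8, BCAT2, FER1 and LNK2 were chosen after their values were seen. The lower genes had a median transcript length of 2538 bp, the higher genes 1279 bp and all tested genes 1755 bp. Both wild-type libraries left in that fit had fewer reads from the shortest transcripts than every athb1-1 library (median log2 deviation −0.09 and −0.08 against −0.03 to 0.07). Transcript length was therefore partly confounded with genotype there. After a trend with transcript length was removed from each library, 15 genes passed with 6 libraries and 106 without wild-type replicate 2, of which 93 were among the 165. Leaving out other libraries ended some calls (edgeR, Benjamini-Hochberg adjusted p). FRO4 did not pass without wild-type replicate 1 (0.0756), athb1-1 replicate 1 (0.0948) or athb1-1 replicate 2 (0.0854). AT5G40720 did not pass without wild-type replicate 1 (0.226), wild-type replicate 3 (0.0907), athb1-1 replicate 1 (0.337) or athb1-1 replicate 2 (0.166). AT5G35940 did not pass without athb1-1 replicate 1 (0.0948) or athb1-1 replicate 3 (0.0826).

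**Figure D2:**
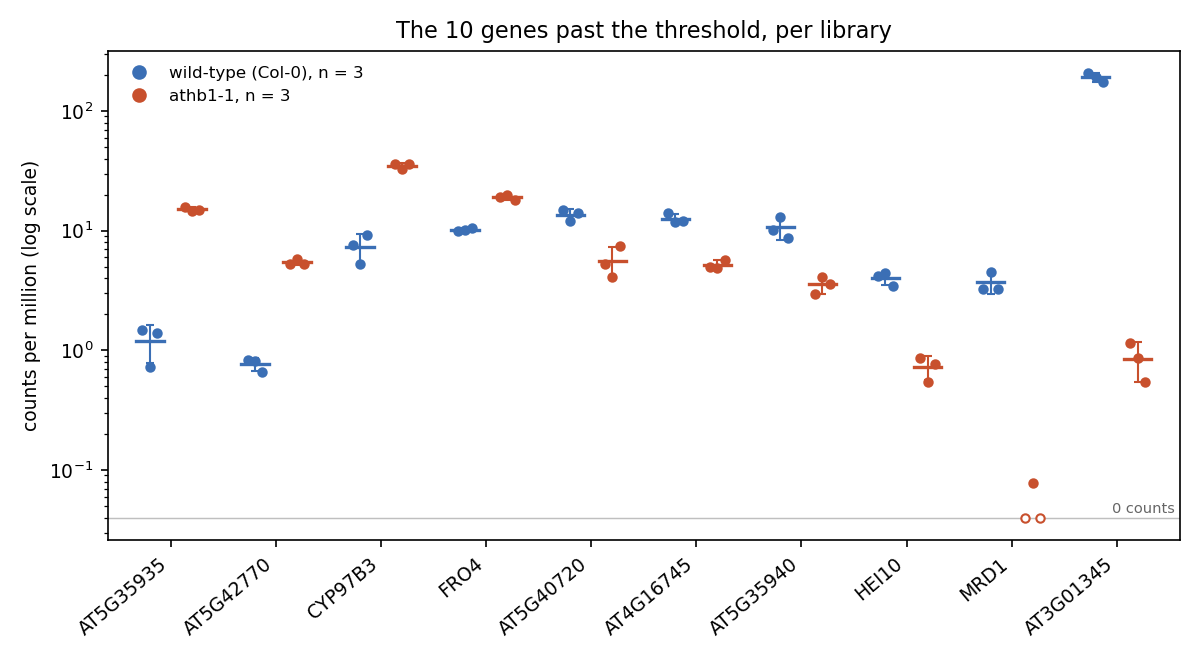
CPM (log scale) of the 10 genes that changed, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3 wild-type in blue, n = 3 athb1-1 in red); open circles stand for 0 counts. The groups do not overlap for any of the 10 genes, and MRD1 had 1 count in all athb1-1 libraries together.

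Lists of PIF-induced, auxin response, HD-Zip I, root hair and glucosinolate genes lay slightly higher in athb1-1 by camera with its preset correlation, and those of carbon starvation, clock and plastid-encoded genes slightly lower. Of 29 lists, 9 passed camera with its preset correlation, 6 up and 3 down, and 15 had an unadjusted camera p under 0.05. None of the 9 passed with an estimated correlation, 0 lists in all. Fry called 2, glucosinolate synthesis (fry adjusted p 0.00250) and Aux/IAA and GH3 auxin response (0.00737). No list had a member past the threshold over all genes. The median log2 fold change of all tested genes was 0.01.

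Root hair genes were higher as a group: 20 of 21 had a positive log2 fold change, with a median of 0.35 (camera adjusted p 8.15e-05; adjusted p = 0.498 with an estimated correlation). Root markers were positive in 11 of 13, with a median of 0.11, and did not pass camera (adjusted p 0.0870), but passed without a filter on low counts (0.0135), without wild-type replicate 2 (0.0471) and without athb1-1 replicate 3 (0.0158). Examples of root hair genes were the xyloglucan enzyme XTH26 at 1.12 (SE 0.36) and the expansin EXPA18 at 0.58 (SE 0.21). Both also belong to other lists, XTH26 to the XTH genes and EXPA18 to the expansins. Glucosinolate synthesis genes were positive in 8 of 8, with a median of 0.26 (camera adjusted p 1.88e-04; adjusted p = 0.258 with an estimated correlation). MAM1, of methionine chain elongation, stood at 0.79 (SE 0.29) and SUR1, a C-S lyase, at 0.24 (SE 0.10). In neither list was a member past 0.05 adjusted over the list alone, a count of 0, and edgeR gave 3 members of each an unadjusted p under 0.05. Both lists also passed without wild-type replicate 2 and with the length trend removed as well (camera adjusted p 1.46e-07 and 0.00242). By fry, the glucosinolate list passed (adjusted p 0.00250) and the root hair list did not (0.411).

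PIF-induced growth genes were positive in 11 of 13, with a median of 0.20 (camera adjusted p 5.76e-04; adjusted p = 0.258 with an estimated correlation). XTH15, a cell wall enzyme, stood at 0.56 (SE 0.10) and was the 1 member past 0.05 adjusted over the list alone, against 0 over all genes. ATHB2, a shade-induced HD-Zip factor, stood at 0.25 (SE 0.09). Aux/IAA and GH3 auxin response genes were positive in 20 of 22, with a median of 0.12 (camera adjusted p 0.00976; adjusted p = 0.258 with an estimated correlation). Among them IAA29 stood at 0.35 (SE 0.14), or 0.20 without wild-type replicate 2, and GH3.2 at 0.34 (SE 0.14), or 0.22 without wild-type replicate 3. IAA29 is also in the PIF-induced list, so these lists are not independent. SAUR genes were positive in 14 of 16, with a median of 0.18 (camera adjusted p 0.00121; adjusted p = 0.456 with an estimated correlation). SAUR66 stood at 0.46 (SE 0.17) and SAUR20 at 0.64 (SE 0.24). Both belong to clusters of close copies, and how reads were divided among these was not tested. The SAUR list did not pass without wild-type replicate 3 (camera adjusted p 0.0840) or athb1-1 replicate 2 (0.131). All 10 tested HD-Zip I genes other than ATHB1 were positive, with a median of 0.18 (camera adjusted p 0.00481; adjusted p = 0.340 with an estimated correlation). ATHB6 stood at 0.28 (SE 0.10) and ATHB16 at 0.17 (SE 0.08). This list did not pass without wild-type replicate 2 (camera adjusted p 0.115) or without a filter on low counts (0.505). With the length trend removed and without wild-type replicate 2, none of these 4 lists passed camera, at adjusted p of 0.0885 for the PIF-induced and Aux/IAA lists, 0.0741 for SAUR genes and 0.225 for HD-Zip I genes.

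Carbon starvation genes were lower as a group, negative in 12 of 12 with a median of −0.14 (camera adjusted p 2.11e-04; adjusted p = 0.545 with an estimated correlation). DIN10, a raffinose synthase, stood at −0.35 (SE 0.10) and DIN6, the dark-induced asparagine synthetase, at −0.36 (SE 0.11). In this list 3 members were past 0.05 adjusted over the list alone, against 0 over all genes. Circadian clock genes were negative in 16 of 19, with a median of −0.16 (camera adjusted p 0.00481; adjusted p = 0.258 with an estimated correlation). The photoreceptor gene LKP2 stood at −0.32 (SE 0.10) and the clock output factor RVE1 at −0.32 (SE 0.11). Plastid-encoded genes were negative in 71 of 80, with a median of −0.36 (camera adjusted p 1.01e-07; adjusted p = 0.616 with an estimated correlation). ATCG00640 stood at −0.75 (SE 0.27) and ATCG00190 at −0.38 (SE 0.15), or at −0.39 and −0.25 without wild-type replicate 2. This list did not pass without wild-type replicate 2 (camera adjusted p 0.779), the library with the highest plastid share of counts. The clock and carbon starvation lists passed without that library and with the length trend removed as well (camera adjusted p 0.00257 and 8.37e-05), but not by fry (adjusted p 0.301 and 0.411).

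**Figure D3:**
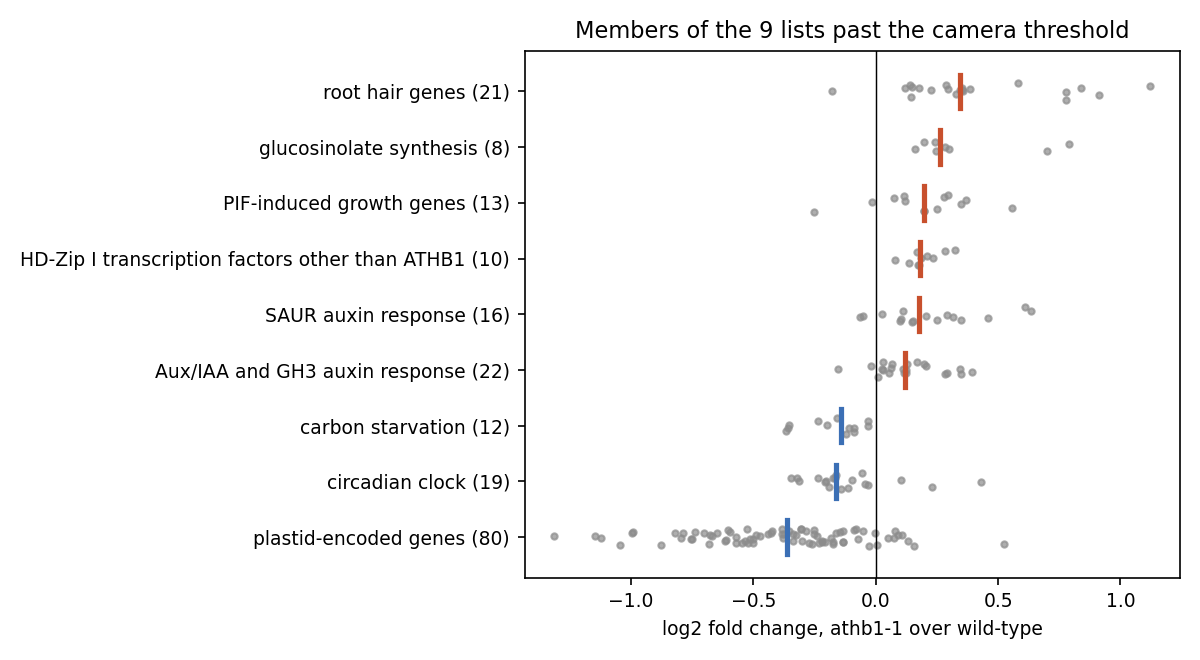
Log2 fold changes (athb1-1 over wild-type) of the members of the 9 lists past the camera threshold with the preset correlation, 1 grey point per tested gene and a coloured bar at each list's median; the number of tested genes stands beside each name. Medians run from −0.36 for plastid-encoded genes to 0.35 for root hair genes, and no list passed with an estimated correlation.

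In the other 20 lists no direction passed camera. Among iron deficiency genes, IRT1, the main root iron transporter, had 4 counts in wild-type and 260 in athb1-1, a ratio of 55.9 (95% counting interval 21.6 to 207). IRT1 was not past the threshold over all genes with 6 libraries (edgeR adjusted p 0.164), but passed without athb1-1 replicate 1 (2.16e-04), without athb1-1 replicate 3 (0.0210) and by the DESeq2 Wald test (4.22e-09). It did not pass in 13 of 17 alternatives, among them those without wild-type replicate 1 (edgeR adjusted p 0.781), wild-type replicate 2 (0.299), wild-type replicate 3 (0.264) or athb1-1 replicate 2. The iron list had a camera adjusted p of 0.0919 with 2 members past 0.05 adjusted over the list alone, IRT1 and FER1, the latter chosen after its values were seen. VSP1, of the jasmonate list, stood at −1.12 (SE 0.20), the tryptophan-metabolising enzyme gene CYP79B2 of the defence list at 0.78 (SE 0.20) and the peroxidase gene PRX34 at −0.43 (SE 0.12). Each was the 1 member of its list past 0.05 adjusted over the list alone, as was XTH15 among XTH genes. Over all genes, VSP1 passed edgeR without wild-type replicate 1 (adjusted p 0.00428) and without wild-type replicate 2 (0.0323), XTH15 without wild-type replicate 2 (0.00120), and both passed DESeq2 (0.00228 and 5.24e-04), while VSP1 did not pass in 11 and XTH15 in 13 of 17 alternatives. Camera adjusted p values were 0.0692 for defence, 0.0919 for XTH genes, 0.238 for peroxidases and 0.430 for jasmonate. They were 0.0692 for mitochondrion-encoded genes, 0.0704 for photosynthesis, 0.0870 for seed storage and for root markers, and 0.119 for flavonoids. They were 0.317 for heat shock, 0.430 for cellulose synthesis, 0.474 each for arabinogalactan proteins, ABA response, gibberellin and expansins, 0.505 for cell division and for phytochrome signalling, 0.631 for touch and cold, and 0.800 for brassinosteroid. Median and mean differed in sign for jasmonate (0.01 and −0.09), cell division (0.01 and −0.03), phytochrome signalling (0.04 and −0.01) and brassinosteroid (−0.02 and 0.05), where camera followed the mean.

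Single libraries decided several of these lists, by camera adjusted p. Without wild-type replicate 2, XTH genes (0.0240), root markers (0.0471) and expansins (0.0338) passed. Without wild-type replicate 3, mitochondrion-encoded genes (3.01e-07), seed storage (5.48e-04), photosynthesis (0.00504), cell division (0.0408) and iron deficiency (0.0463) passed. ABA response passed without wild-type replicate 1 (0.0108). Without athb1-1 replicate 1, iron deficiency (0.0352) and seed storage (0.00170) passed. Photosynthesis (0.00308) and mitochondrion-encoded genes (0.0494) passed without athb1-1 replicate 2. Without athb1-1 replicate 3, photosynthesis (0.0224), mitochondrion-encoded genes (0.0327), root markers (0.0158) and XTH genes (0.0325) passed. With all libraries kept, photosynthesis passed with the length trend removed (0.0279) and mitochondrion-encoded genes with a replicate block (0.00671). Seed storage passed without a filter on low counts (1.67e-04) and with a replicate block (0.0386).

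**Figure D4:**
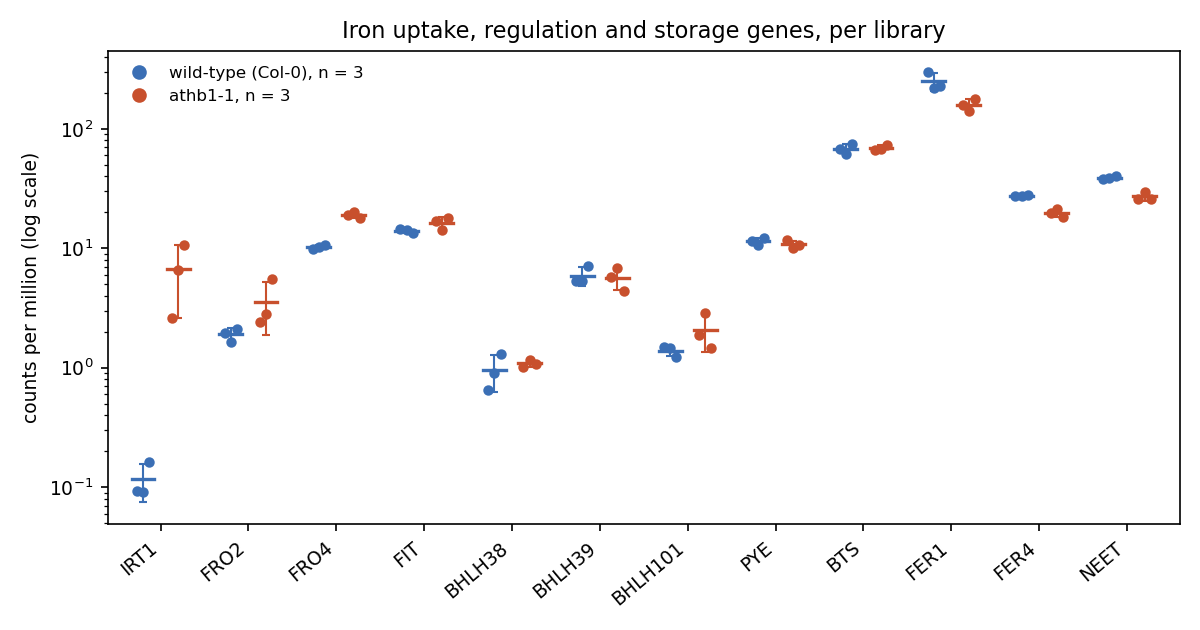
CPM (log scale) of iron uptake, regulation and storage genes and of FRO4, whose metal was not tested, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3 wild-type in blue, n = 3 athb1-1 in red). FRO4, which is not in the fixed iron list, passed the threshold over all genes, and IRT1 had 4 counts in wild-type and 260 in athb1-1.

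Exon usage differed at ATHB1 itself. Relative to the locus as a whole, exon 1 was higher in athb1-1 by 0.71 on the natural log scale (edgeR adjusted p over bins 0.00139). Exon 1 kept 4.28% of its wild-type level, against 0.901%, 1.03% and 1.08% for exons 2, 3 and 4. Of 12808 genes with 82457 bins tested, ATHB1 was the 1 gene past the threshold (Simes p, Benjamini-Hochberg adjusted p 9.11e-04), and 79 had an unadjusted Simes p under 0.05. The gene-level F-test called 2, ATHB1 and AT2G41640 (adjusted p 0.00706), the latter chosen after its values were seen. The count of the Simes test was 0 without athb1-1 replicate 1, without athb1-1 replicate 2 and without athb1-1 replicate 3.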

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

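Removal of the length trend, its combination with wild-type replicate 2 left out, and summed exon bins were chosen after the data were seen; the other alternatives were planned. ATHB1 kept its direction and its call in all 14 alternatives run for it, from −5.61 to −5.48. With either other normalization, the stricter filter, organelle genes left out and limma-voom, the test again called 10 genes, the same 10; summed bins called 12, among them those 10. No gene named by the rule turned direction in any alternative. Without a filter 19 genes passed (10 higher); with the DESeq2 Wald test 22 passed (12 higher, 10 lower); the cause was not tested. With the length trend removed and without wild-type replicate 2, 106 genes (53 higher, 53 lower) and 4 lists passed; the cause was not tested. Camera with an estimated correlation called 0 lists and fry 2, against 9 by camera with the preset correlation, where 15 had an unadjusted p under 0.05; the cause was not tested. With each library left out in turn, the counts ran from 8 to 165 genes, 3 to 71 higher and 4 to 94 lower, and from 0 to 1 for exon usage, whose F-test gave 2. Explanations for the 165, which came without wild-type replicate 2, are weighed with that library, and for the other values the cause was not tested. With a replicate block 12 genes and 11 lists passed, and IRT1 had an edgeR adjusted p of 4.41e-06. Profiles with the same replicate number correlated at −0.05, 0.21 and 0.11 across genes, which are not independent replicates. Profiles with different numbers correlated at −0.21 to 0.16. With 3 libraries per genotype, these values cannot decide whether replicate numbers pair the libraries. Lists that turned direction passed neither with all 6 libraries nor in the setting that turned them, though some passed in other settings (camera adjusted p): touch and cold without a filter (0.742); cellulose (0.361), brassinosteroid (0.968), ABA (0.734), cell division (0.642) and mitochondrion-encoded genes (0.467) with the length trend removed and without wild-type replicate 2. With libraries left out, lists that turned ran over 0.0108 to 0.931 (ABA), 0.0904 to 0.716 (arabinogalactan), 0.733 to 0.986 (brassinosteroid), 0.0408 to 0.784 (cell division), 0.0338 to 0.941 (expansins), 0.114 to 0.918 (gibberellin), 0.288 to 0.881 (heat shock), 3.01e-07 to 0.707 (mitochondrion), 0.00308 to 0.784 (photosynthesis), 0.0587 to 0.986 (phytochrome) and 0.298 to 0.969 (touch and cold); the cause was not tested. Depth limits genes of few counts, such as IRT1 with 4 counts in wild-type.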

Other observations

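Genes of iron uptake and storage, and FRO4 beside them, were looked at one by one, since the iron list did not pass camera (adjusted p 0.0919). FRO4, FER4 and NEET were outside that list. Which metal FRO4 serves was not tested, so its rise alone says nothing of iron. Besides FRO4 and IRT1, the root ferric reductase FRO2 stood at 0.89 (SE 0.32, log2 fold change), with all athb1-1 libraries above wild-type, but at 0.44 (SE 0.25) without athb1-1 replicate 3. The ferritin genes FER1 and FER4 stood at −0.65 (SE 0.13) and −0.49 (SE 0.10), and the iron-sulfur protein gene NEET at −0.52 (SE 0.10), all with athb1-1 libraries below wild-type. The regulators FIT (0.23), BHLH38 (0.17), BHLH39 (−0.06), BHLH101 (0.58), PYE (−0.09) and BTS (0.03) had overlapping groups. With libraries left out in turn, BHLH38 ran from −0.04 without wild-type replicate 1 to 0.47 without wild-type replicate 3, BHLH39 from −0.21 without athb1-1 replicate 2 to 0.10 without wild-type replicate 3, and BTS from −0.04 without wild-type replicate 2 to 0.10 without wild-type replicate 3. PYE ran from −0.15 without athb1-1 replicate 1 to −0.04 without wild-type replicate 3, and BHLH101 stood at 0.27 without athb1-1 replicate 2. With all 6 libraries FRO4 alone of these passed edgeR over all genes, and it did not pass without wild-type replicate 1 (adjusted p 0.0756), athb1-1 replicate 1 (0.0948) or athb1-1 replicate 2 (0.0854). Without wild-type replicate 2, FER1 (edgeR adjusted p 0.0198), FER4 (0.0175) and NEET (0.00661) passed, and NEET also passed with the length trend removed (0.0364). IRT1 passed without athb1-1 replicate 1 (edgeR adjusted p 2.16e-04), without athb1-1 replicate 3 (0.0210) and by DESeq2 (4.22e-09), but not in 13 of 17 alternatives, among them those without wild-type replicate 1 (edgeR adjusted p 0.781), wild-type replicate 2 (0.299), wild-type replicate 3 (0.264) or athb1-1 replicate 2. FRO2, FER1, FER4, NEET and the 6 regulators were chosen after their values were seen.

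The table of the authors calls 48 genes at an adjusted p under 0.05, 24 in each direction, and 46 of them were tested here. It holds all 10 genes called by the edgeR quasi-likelihood test, and its log2 fold changes correlate at 1.00 with those computed here across 18626 genes, which are not independent replicates. Both rest on the same libraries, so the match is no independent support for the calls. Genes called in that table and not by the edgeR quasi-likelihood test on all 6 libraries include IRT1, VSP1, XTH15, FER1, the arginase ARGAH2, the sodium transporter HKT1, the sucrose transporter SWEET12, the indole glucosinolate methyltransferases IGMT2 and IGMT3, and the near-identical glutathione transferases GSTF6 and GSTF7, whose reads are uncertain. FER1, ARGAH2, HKT1, SWEET12, the IGMT and the GSTF genes were chosen after their values were seen. The seed storage genes SESA3 and CRU3, also in that table and chosen after their values were seen, had 130 and 79 counts in wild-type replicate 2 and at most 4 in any other library.

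In this part, the tests of shared reads, of the ATHB1 region, of neighbouring genes, of the length trend, of ungerminated seeds, of root share and of iron supply were chosen only after the result was seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 10 genes and the highest other 43, and 2 of the 10 splits called as many as the real one. That other split sets wild-type replicates 1 and 3 and athb1-1 replicate 3 against the rest, the same parting as the length trend and the ratio of last to first exon, and points to a structure of the samples; it called 31 with the length trend removed. For lists the real split gave 9 and the highest other 12, with 4 splits as high; for exon usage the values were 1 and 0, with 1 split as high.

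Called genes lay side by side: 4 of 10 had another within 10 kb, in 2 pairs, and 0 of 10000 random sets of tested genes had as many (1e-04, the smallest share they can give). Reads shared with MRD1 are argued against for HEI10, whose exon 9, the longest that touches no other gene model and a bin in which each read counts once, had 44 counts in wild-type (12 to 17 per library) and 8 in athb1-1 (1 to 4), a ratio of 6.19 (95% counting interval 2.88 to 15.2). Shared reads are also argued against for AT5G35940, which stood at −1.58 beside the higher AT5G35935, 682 bp away. A block of sequence carried along with the mutation is argued against as the whole cause, since 1 of the 10, AT3G01345 at 51.6 kb, lies within 500 kb of ATHB1 (Fisher's exact test, two-sided, p = 0.0896). Local differences between the stocks, in sequence or silencing, may underlie the pairs and cannot be told apart from genotype, and an HD-Zip site within 1 kb upstream, in 0% of called and 2.33% of other genes (Fisher's exact p = 1), is too rare for 10 genes to decide.

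Wild-type replicate 2 stood apart, and without it 165 genes passed in place of 10. A transcript length trend is argued against as the whole cause, since with it removed 15 genes passed with all 6 libraries and 106 without that library. RNA of ungerminated seeds stays open: storage genes reached 55.8 CPM there, while the late embryo genes EM1, EM6 and PER1 summed to 3.73 CPM, within the 1.95 to 7.81 CPM of the other 5 but on too few counts to decide. Broken RNA could have contributed: the median log2 ratio of last to first exon over 951 genes was the highest of the 6 at 0.108, but athb1-1 replicate 2 reached 0.0908, so it stays open. Apart from ungerminated seeds, no biological explanation was tested, as the design gives none for a single library.

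FRO4 was higher in athb1-1, and IRT1 and FRO2 had all athb1-1 libraries above wild-type without passing over all genes. A larger share of root alike in all its tissues is argued against as the whole cause for FRO4 and IRT1, since the 13 root markers had a median of 0.107 (bootstrap SE 0.0413), and with any library left out the bounds of FRO4 (at least 0.590) and IRT1 stayed above that of the markers (at most 0.294, 2 SE). For FRO2 it stays open, since its lower bound reached −0.0661 without athb1-1 replicate 3, as do more root hair cells, whose genes were positive in 20 of 21 and which were not tested. Less iron reaching the mutant seedlings might lower ferritins, which FER1 and FER4 show in direction, but the regulators BHLH38, BHLH39, BHLH101, PYE and BTS had a median of 0.0304, and growth plates cannot be told apart from genotype here. An effect of the athb1-1 genotype stays open, as untested.

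A hypothesis written before its test was that loss of ATHB1 shifts genes with an upstream HD-Zip site. The 432 tested genes with such a site had a median log2 fold change of 0.0149 and the others 0.00702, a difference of 0.00785 (permutation test with 100000 permutations, two-sided, p = 0.376). The test named no size of shift in advance, and a p that misses the threshold bounds none, so the hypothesis stays open.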
